A study of Homo sapiens with 12 samples.

How the data were processed

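RNA from 2 human multiple myeloma cell lines, KMS12 and SKMM1, was compared on 12 dual-colour Agilent expression arrays. Both lines carried an inducible short hairpin RNA (shRNA) against IRF4, a transcription factor of B cells and plasma cells. Per the labels, Cy3 held RNA of untreated cells on every array, and Cy5 held RNA of the same line after 2, 4 or 6 days of doxycycline at 20 ng/ml. No array had the dyes swapped. A probe's own dye bias therefore stays in each comparison with untreated RNA, and cancels in the difference between lines and between days. The series describes 3 time courses, 2 of KMS12 and 1 of SKMM1, with technical repeats inside each course. KMS12 had 8 arrays, of which 2 were from day 2, 3 from day 4 and 3 from day 6. SKMM1 had 4 arrays, of which 1 was from day 2, 1 from day 4 and 2 from day 6.

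The deposited scanner files hold spot intensity on a linear scale for both channels, made with Agilent Feature Extraction, per the file headers. The headers give version 9.5.1.1 and the submitters' processing notes give version 9.1.3.1. The same deposited files hold a log10 ratio of Cy5 over Cy3 for each spot, and the genome build is hg17, per the file headers. The authors also deposited a value table on a log10 scale. Its columns correlated with the log10 ratios of the matching scanner files at r between 0.672 and 0.985, so scale and direction were settled from the values, and between 40.0% and 62.1% of spots were equal within 0.0006. Its column medians were -0.015, 0.00, 0.00, -0.029, -0.037, -0.033, -0.037 and -0.030 for KMS12 (day 2 replicate 1, day 4 replicates 1 and 2, day 6 replicate 1, day 2 replicate 2, day 4 replicate 3, day 6 replicates 2 and 3). For SKMM1 they were -0.020, -0.032, -0.016 and -0.016 (day 2, day 4 and both day 6 arrays). How the authors centred the table stays unknown.

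Mean spot intensities were background corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with the data.table package at version 1.17.8. Each array had 45015 spots, of which 1639 were controls. Spots marked as outliers were set to missing, and spots of the same probe were averaged, giving 41000 probes. A probe was kept when well above background in either channel on at least 3 arrays, which left 31827. The brightest probe stood for each gene. Of the probes, 23434 were named through their accession, 2317 through a current symbol and 1040 through an older symbol, and 14209 kept the name in the file. In all 23892 genes or transcripts were tested, 14851 of them with a RefSeq symbol. Among 5985 genes with several kept probes, 16 had probes that passed the test in opposite directions in KMS12, among them RPS2 and APLN.

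Between 56.3% and 68.8% of spots were well above background in Cy3 and between 67.1% and 75.1% in Cy5, with 0 saturated spots. Median intensities lay between 106.9 and 280.1 in Cy3 and between 179.3 and 334.4 in Cy5. The number of arrays limits the precision of every value. Probes well above background on no array of a line have only a bound there and are given no difference between lines, and where only some arrays measured a gene named for a line difference, their number is given. Where a bound is given, "at least N-fold" sets the mean of the bright channel against the higher of the dim probe's own signal and the lowest signal called well above background on each array. These bounds were taken per channel after loess and Aquantile and stay open to dye bias.

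Technical repeats were averaged before fitting. The design fixed before the data were examined named the day 4 replicates 1 and 3 of KMS12 and both day 6 arrays of SKMM1. Day 6 replicates 2 and 3 of KMS12 turned out to be as close (r = 0.953) as the SKMM1 repeats (r = 0.943) and were also counted as 1 sample. This departs from the list fixed beforehand, and it was settled after the counts under both handlings had been seen. Counts under the handling listed beforehand stand beside the results. The fits then held 9 samples, 6 of KMS12 and 3 of SKMM1. Single days of KMS12 were tested against 0 in a fit of 6 group means with 3 residual degrees of freedom. Line averages over the 3 days, the line difference and day 6 minus day 2 came from an additive fit of line and day with 5 residual degrees of freedom. Tests used limma's lmFit and eBayes on log2(Cy5/Cy3) with Benjamini-Hochberg adjustment over all genes at 0.05. SEs and p-values below come from these fits. The untreated RNA is the control on each array, so its differences between arrays enter the spread of the ratios. Where arrays shared untreated RNA its own spread would be left out, and the labels used here do not say whether they did. The p-values measure only the spread between these samples. Each fit pools this spread over both lines, so the p-values of a line rest in part on the samples of the other line. The KMS12 samples come from 2 courses and the SKMM1 samples are 3 days of a single course.

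Before the data were examined, 20 gene lists, the tests and the rule for named genes were fixed. The lists were plasma cell identity, mature B cell identity, MYC targets and ribosome biogenesis, G2 and mitosis, DNA replication, cholesterol and fatty acid synthesis, glycolysis, the unfolded protein response, ATF4 targets of the integrated stress response, p53 targets, apoptosis regulators, interferon-stimulated genes, NF-kB targets, ribosomal proteins, oxidative phosphorylation, replication-dependent histones and immediate early genes, and markers of T and NK cells, of monocytes and macrophages, and of stroma and epithelium. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment was over the 20 lists of a comparison. Genes named are IRF4 and MYC and, among called genes with the same sign on every array of the line, the 8 largest rises and falls in each line. Named too are the 8 shared rises and falls with the largest smaller change, the 6 largest line differences each way and up to 4 called members of each list. Accessions, uncharacterised loci, Y-linked genes and XIST were left out. Not every gene that this rule names is reported here.

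The arrays lay on 3 slides. Slides 1 and 2 each held 4 KMS12 arrays from all 3 days and slide 3 held all SKMM1 arrays, so slide and line cannot be told apart. Slide was tried as a block within KMS12, and KMS12 was fitted within each slide. Other alternatives changed the background correction, the within-array and between-array normalization, the source of the values, the filter on dim probes, the probe rule, the variance prior, the averaging of repeats, the samples in the fit and the list test, and left out each array in turn. In simulated data with 23892 genes, the KMS12 average recovered 67.2%, 98.5% and 100% of genes changed by log2 0.5, 1 and 2. The SKMM1 average recovered 26.9%, 94.0% and 98.5%, the line difference 5.97%, 85.1% and 98.5%, and day 6 minus day 2 1.49%, 52.2% and 97.0%. False calls were 14 of 191, 6 of 152, 9 of 135 and 3 of 103 in that order. The simulated noise was independent for each sample. Likeness of samples within a course or slide was thus left out, and recovery may be overstated.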

Results

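The arrays asked which genes changed when IRF4 was lowered in myeloma cells, over 6 days and in 2 lines, KMS12 and SKMM1. Every array used the same hairpin, and no array held a control hairpin or doxycycline alone. Effects of doxycycline or of the hairpin itself therefore cannot be told apart from those of lower IRF4. Each array compared induced cells in Cy5 with untreated cells of the same line in Cy3, so a negative log2 ratio means a lower level in induced than in untreated cells. Unless a channel is named, rises and falls below are those of this ratio, and the change behind them may lie in either channel. KMS12 gave 8 arrays counted as 6 samples and SKMM1 gave 4 arrays counted as 3 samples. The day 6 arrays of SKMM1 (r = 0.943 over genes) and day 6 replicates 2 and 3 of KMS12 (r = 0.953) were each counted as 1 sample, as were day 4 replicates 1 and 3 of KMS12, which lay on different slides and correlated at r = 0.432. The arrays labelled KMS12 day 4 replicate 2 and day 6 replicate 1 were closer than any of these (r = 0.984) and were kept as 2 samples. Other KMS12 arrays of the same day on different slides agreed little. They correlated at r = 0.311 at day 2, 0.362 at day 4 (replicates 2 and 3) and 0.255 and 0.256 at day 6. Over all pairs of a slide 1 and a slide 2 array r ran from -0.047 to 0.659.

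IRF4, the target of the shRNA, was lower in the induced channel on 12 of 12 arrays. In KMS12 it fell by 0.76 on the log2 scale (SE 0.15, SD 0.42, n = 6, adjusted p = 0.0164), or 1.69-fold. In SKMM1 its mean was -0.46 (SE 0.21, SD 0.36, n = 3, adjusted p = 0.364), which did not pass the test. Single arrays ran from -1.17 to -0.08 in KMS12 and from -0.85 to -0.14 in SKMM1. The probe lies on chromosome 6 at 356001 to 356061 (hg17), and a second probe at 352535 to 352594 was lower on 7 of 8 KMS12 and 4 of 4 SKMM1 arrays. MYC, a growth-promoting transcription factor, was lower on 12 of 12 arrays by its brightest probe on chromosome 8 (128822450 to 128822509). It fell by 0.62 in KMS12 (SE 0.08, n = 6, adjusted p = 0.00534) and by 0.66 in SKMM1 (SE 0.11, n = 3, adjusted p = 0.0351), and a MYC probe at 128817639 to 128817698 was lower on 8 of 8 and 4 of 4 arrays, while another at 128816997 to 128817056 was lower on 3 of 8 and 1 of 4. Within slides, KMS12 arrays averaged -1.04 for IRF4 on slide 1 and -0.27 on slide 2, and -0.75 and -0.45 for MYC. The IRF4 call in KMS12 was lost without day 2 replicate 1 (adjusted p = 0.0658) or day 4 replicate 2 (adjusted p = 0.0613). The MYC call in SKMM1 was lost without KMS12 day 2 replicate 1 (0.0825), KMS12 day 4 replicate 2 (0.0573), SKMM1 day 2 (0.214) or SKMM1 day 4 (0.225). Without both near-identical arrays IRF4 in KMS12 was -0.51 (adjusted p = 0.0806). Median centring in place of loess moved the median of all genes to 0.30 in KMS12 and 0.17 in SKMM1. Relative to that shift IRF4 in KMS12 was -0.45 and MYC -0.08, where the values themselves were -0.14 (adjusted p = 0.462) and 0.23, the latter turned in sign. MYC in SKMM1 was -0.28 and no longer past the test (adjusted p = 0.627).

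**Figure D1:**
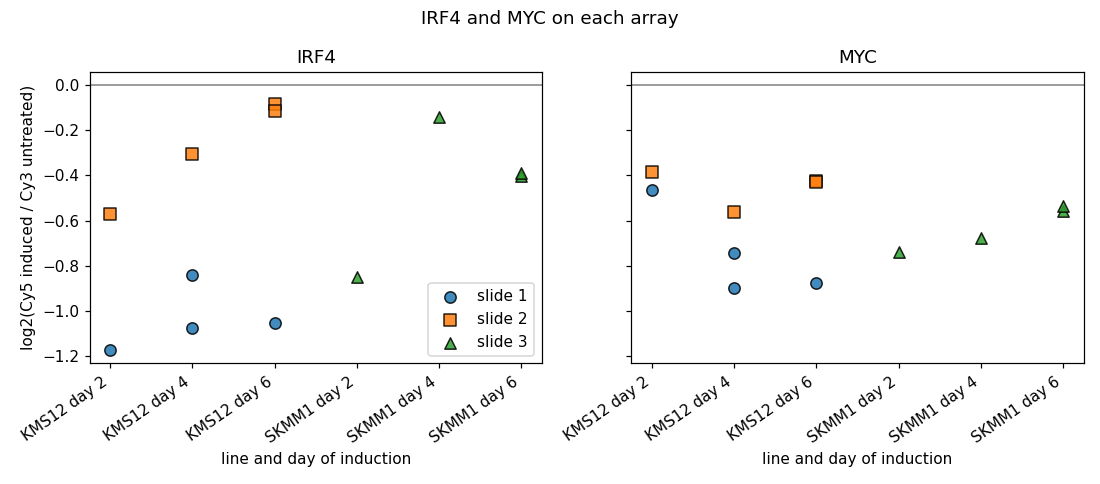
Log2 ratio of induced (Cy5) over untreated (Cy3) RNA for IRF4 and MYC on each of the 12 arrays, by line and day of induction, with each symbol a slide. All points lie below 0, and IRF4 reaches -1.17 on slide 1 and stays between -0.57 and -0.08 on slide 2.

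In KMS12 averaged over the 3 days, TNFRSF17, the plasma cell survival receptor BCMA, fell 5.33-fold (log2 -2.42, SE 0.22, n = 6, adjusted p = 0.0021), and POU2AF1, a B cell transcriptional coactivator, fell 4.35-fold (log2 -2.12, SE 0.21, adjusted p = 0.0025). AMPD1, an AMP deaminase, fell furthest, 7.56-fold (log2 -2.92, SE 0.28, adjusted p = 0.00227). The log2 ratio was -2.32 for PLAAT2, -2.18 for the arginine synthesis enzyme ASS1, -2.01 for INHBE, -1.97 for the glycolytic regulator PFKFB4 and -1.97 for the stress factor ATF3, all of which fell. Lymphotoxin beta, LTB, rose 8.33-fold (log2 3.06, SE 0.47, adjusted p = 0.00858). Both near-identical arrays raise this average. Their untreated log2 intensity of LTB was 11.7, against 13.6 to 15.2 on the other KMS12 arrays. In the induced channel they stood at 17.0, within the 16.3 to 17.0 of the others. LEFTY1, LST1, FAM43A, the perforin gene PRF1, CYTH4, the interferon-induced GTPase GBP4 and the matrix protease MMP11 rose by log2 2.26, 1.80, 1.76, 1.75, 1.72, 1.70 and 1.62.

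In all 3731 of 23892 genes passed in KMS12, 1978 higher and 1753 lower, with 71 and 74 of them at least 2-fold. Counting day 6 replicates 2 and 3 as 2 samples, as listed beforehand, gave 5126 genes. Slide as a block gave 4773 genes. The number was 988 in KMS12 fitted alone, 6308 with all 12 arrays as separate samples and 16655 with median centring. Within slides, limma called 2459 genes on slide 1 and 0 on slide 2, where 4041 had an unadjusted p under 0.05. The count was 1274 without day 2 replicate 1, 1079 without day 4 replicate 2 and 1698 without day 6 replicate 1. INHBE and PFKFB4 were lost without day 2 replicate 1, day 4 replicate 1, day 4 replicate 2 or day 6 replicate 1, and the other 14 named genes passed with each array left out. Without both near-identical arrays the count was 970.

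Genes of the integrated stress response, targets of ATF4 in amino acid synthesis and transport, were lower together in induced than in untreated KMS12 cells. Of 37 measured members 28 fell and 0 rose (31 and 0 adjusted over the list alone), with a median of -0.73 (camera, adjusted p = 2.29e-16, and adjusted p = 0.21 with an estimated correlation). ATF3, CHAC1 and CTH were 3.91-fold, 3.21-fold and 3.13-fold lower. At day 2 their log2 ratios were -0.45, -0.54 and -0.21 (n = 2). They were -2.56, -2.24 and -2.24 at day 4 and -2.89, -2.27 and -2.49 at day 6 (n = 2 each). The list's median was -0.996 within slide 1, -0.43 within slide 2 and -0.66 with slide as a block. In the untreated channel the list's median was 1.28 higher at day 6 than at day 2 on slide 1 and 0.57 higher on slide 2, while in the induced channel it was 0.07 and 0.01 higher.

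Cholesterol and fatty acid synthesis fell in KMS12 with 21 of 33 members lower and 0 higher (27 and 0 adjusted over the list alone, median -0.40, camera adjusted p = 2.61e-15, adjusted p = 0.0946 with an estimated correlation). HMGCS1, which makes HMG-CoA, the sterol sensor partner INSIG1 and squalene epoxidase SQLE fell by 0.84, 0.80 and 0.70. The median in the untreated channel was 0.25 and 0.57 higher at day 6 than at day 2 on slides 1 and 2, and in the induced channel -0.07 and 0.17. This call ended with median centring in place of loess, which gave a median of -0.04 relative to all genes.

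Plasma cell identity fell in KMS12, with 9 of 27 members lower and 4 higher over all genes and adjusted over the list alone (median -0.09, adjusted p = 0.025, adjusted p = 0.193 with an estimated correlation). SLAMF7 and GPRC5D, surface proteins of plasma cells, fell by 1.75 and 1.16. MYC targets and ribosome biogenesis fell with 13 of 44 members lower and 0 higher (15 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.000664, adjusted p = 0.297 with an estimated correlation), RRS1 by 0.46. DNA replication fell with 11 of 40 lower and 3 higher (15 and 4 adjusted over the list alone, median -0.15, adjusted p = 0.00139, adjusted p = 0.164 with an estimated correlation), CDC45 and MCM4 by 0.43 and 0.41. Glycolysis had 5 of 23 lower and 3 higher (9 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.0142, adjusted p = 0.609 with an estimated correlation), and lost its call without day 2 replicate 2 (0.074). The unfolded protein response had 6 of 35 lower and 1 higher (8 and 1 adjusted over the list alone, median -0.14, adjusted p = 0.0142, adjusted p = 0.573 with an estimated correlation) and lost its call without day 4 replicate 2 (0.0634). The chaperone PDIA6 fell by 0.51 and the translocon subunit SEC61B rose by 0.70. Median centring in place of loess turned these directions, with medians relative to all genes of 0.14, 0.16, 0.22, 0.23 and 0.25 in the order given, of which MYC targets, DNA replication and the unfolded protein response passed as higher. Plasma cell identity also lost its call with the strict filter on dim probes and with a trended variance prior. Glycolysis lost its call with the handling listed beforehand, and it and the unfolded protein response lost theirs without the near-identical arrays.

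Ribosomal protein genes rose in KMS12, 20 of 51 members against 2 lower (29 and 4 adjusted over the list alone, median 0.30, camera adjusted p = 4.17e-06, adjusted p = 0.297 with an estimated correlation), RPS21 by 0.76. Interferon-stimulated genes rose, 13 of 41 against 1 lower (15 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.000278, adjusted p = 0.164 with an estimated correlation), with SP110, IFITM1 and IFI6 at 1.26, 1.02 and 0.97. Replication-dependent histones rose, 9 of 22 against 0 lower (12 and 0 adjusted over the list alone, median 0.26, adjusted p = 0.000258, adjusted p = 0.484 with an estimated correlation), with H2BC9 at 0.58 and H2BC12 at 0.49. Markers of T and NK cells rose, 4 of 21 against 0 lower (5 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.0118, adjusted p = 0.193 with an estimated correlation), led by PRF1 at 1.75 and CD2 at 0.88. Median centring ended the interferon call (adjusted p = 0.0668) and turned the T and NK markers to -0.24 relative to all genes. The authors' value table and the Feature Extraction ratio ended the ribosomal protein call.

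Of 75 list members that the rule names in KMS12, 39 passed with each array left out, and the members given as examples for KMS12 lists were picked from those after their values were seen. The call was lost for 31 without day 2 replicate 1, 33 without day 4 replicate 2, 25 without day 6 replicate 1, 10 without day 2 replicate 2 and 11 without day 4 replicate 1, and for 7 and 11 without SKMM1 day 2 and day 4. Members lost without day 2 replicate 1 include the glycolytic genes HK2 (-1.01, adjusted p = 0.0556 without it), ALDOC (-0.88, 0.0562) and SLC2A1 (-0.82, 0.0738), the replication licensing factor CDT1 (-0.89, 0.0796), the stress proteins HERPUD1 (-0.70, 0.0512) and CREB3L2 (-0.41, 0.0851), and the ribosomal protein genes RPL6 (0.86, 0.114) and RPL34 (0.85, 0.0839).

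The other 9 lists did not pass in KMS12. Their medians were 0.01 for mature B cell identity (adjusted p = 0.958), -0.03 for G2 and mitosis (0.129), 0.00 for p53 targets (0.832), 0.06 for apoptosis regulators (0.757), 0.08 for NF-kB targets (0.632), 0.05 for oxidative phosphorylation (0.612), -0.03 for immediate early genes (0.167), -0.02 for monocyte and macrophage markers (0.751) and 0.03 for stromal and epithelial markers (0.757). Members past the test over all genes, higher and lower, were 2 and 3, 0 and 5, 6 and 4, 3 and 7, 5 and 2, 7 and 3, 2 and 5, 2 and 1, and 2 and 1 in that order, and adjusted over the list alone 2 and 3, 0 and 4, 8 and 7, 4 and 8, 8 and 4, 8 and 4, 3 and 5, 2 and 1, and 2 and 1. Median centring turned G2 and mitosis to 0.31, mature B cell identity to -0.17 and stromal markers to -0.44 relative to all genes, and called G2 and mitosis, apoptosis regulators (0.36) and oxidative phosphorylation (0.45). Camera's direction was opposite to the median for mature B cell identity and for apoptosis regulators, and to the mean of 0.06 for p53 targets. Members that changed among them include the cell cycle inhibitor CDKN1A and the p53 targets SESN1 and TP53INP1 (rises of 0.68, 0.94 and 1.08), the death regulators BMF, BCL2L11 and TNFSF10 (1.01, 0.70 and 0.85), TNF (0.95), the chemokine CCL3 (-1.21), the orphan receptor NR4A1 (-1.71) and fibronectin FN1 (1.11). With the filter asking for both channels on every array TNF turned to -0.22 (adjusted p = 0.0844).

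Within slides 1 and 2, KMS12 medians were -0.21 and -0.10 for plasma cell identity, -0.18 and -0.18 for MYC targets, -0.11 and -0.14 for DNA replication, -0.50 and -0.37 for cholesterol synthesis, -0.28 and -0.13 for glycolysis and -0.17 and -0.04 for the unfolded protein response. For ribosomal proteins they were 0.33 and 0.23, for interferon-stimulated genes 0.17 and 0.15, for histones 0.18 and 0.41 and for T and NK markers 0.13 and 0.08. With slide as a block the medians of these 10 lists were -0.09, -0.14, -0.14, -0.39, -0.17, -0.11, 0.30, 0.14, 0.28 and 0.12, and all 11 lists kept their call.

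**Figure D2:**
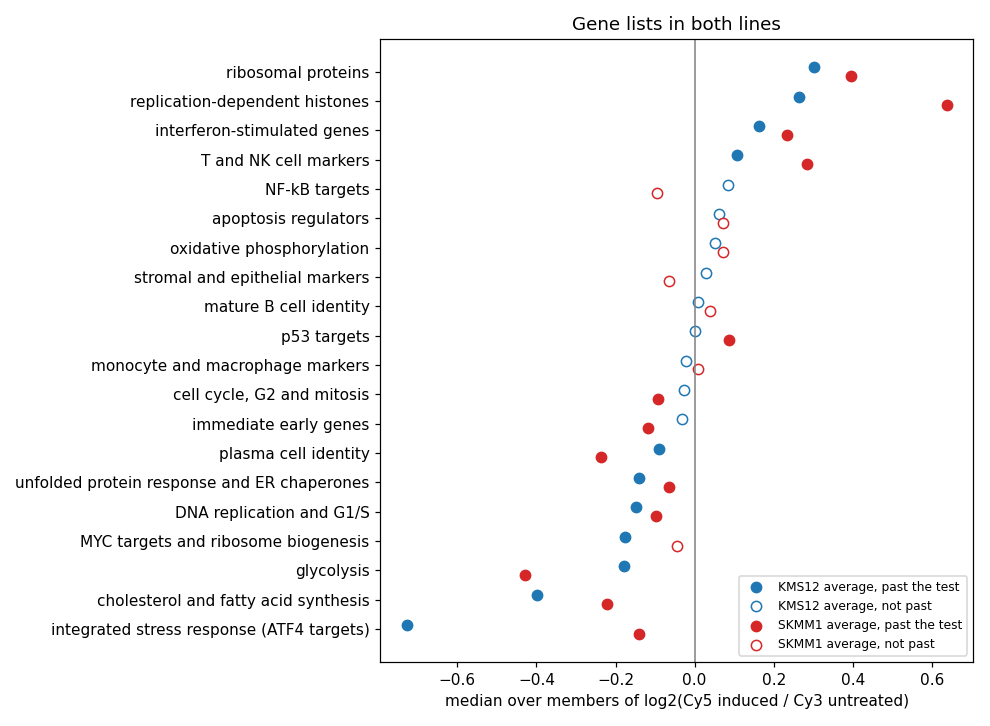
Median over the members of each of the 20 gene lists of log2(Cy5 induced / Cy3 untreated), for the KMS12 average (n = 6) and the SKMM1 average (n = 3), with filled points past camera's test at a preset correlation of 0.01. ATF4 targets reach -0.73 in KMS12 and -0.14 in SKMM1, and histones 0.26 and 0.64.

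SKMM1 averaged over the 3 days showed rises of granzymes and falls of KLF2 and adrenomedullin. GZMB, the granzyme B gene of cytotoxic cells, rose 5.69-fold (log2 2.51, SE 0.08, n = 3, adjusted p = 2.32e-05) and GZMA rose 4.06-fold (log2 2.02, SE 0.09, adjusted p = 0.000175). Both SEs rest in part on KMS12, where the day means of both genes lay between -0.035 and 0.151. There GZMA and DMBT1, given below, were well above background in neither channel. In SKMM1 itself GZMA stood at 1.69, 2.30 and 2.08 at days 2, 4 and 6, so these SEs and p-values may understate the spread within SKMM1. The lymphocyte homing receptor CCR7 rose 4.68-fold (log2 2.22, SE 0.13, adjusted p = 0.000664). FXYD2, the signalling exchange factor VAV3, NMI, the inflammatory caspase CASP1 and DMBT1 rose by log2 1.82, 1.74, 1.66, 1.49 and 1.44. The transcription factor KLF2 fell 5.45-fold (log2 -2.45, SE 0.37, adjusted p = 0.0228) and the peptide hormone gene ADM 5.39-fold (log2 -2.43, SE 0.39, adjusted p = 0.0263). CPXM2, the arginase ARG2, IGSF21, ANGPTL4 and the protein C receptor PROCR fell by 1.67, 1.59, 1.53, 1.51 and 1.47.

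In all 437 genes passed in SKMM1, 218 higher and 219 lower, with 33 and 31 at least 2-fold. The handling listed beforehand gave 752, slide as a block 675 and the SKMM1 slide fitted alone 620. The count was 13 without SKMM1 day 4, 215 without SKMM1 day 2, 177 without KMS12 day 2 replicate 1 and 217 without KMS12 day 4 replicate 2. With every array kept it ran from 98 with the value table to 1808 with all 12 arrays as separate samples, with 102 under the strict filter on dim probes, 189 with the Feature Extraction ratio and 969 with scale normalization. Without SKMM1 day 4 the calls of NMI, CASP1, KLF2, ADM, ARG2, IGSF21 and ANGPTL4 were lost. CASP1 and KLF2 were lost without SKMM1 day 2, KLF2 and IGSF21 without KMS12 day 2 replicate 1, and ADM and IGSF21 without KMS12 day 4 replicate 2. The other 8 named genes passed with each array left out.

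Of 33 list members that the rule names in SKMM1, GZMB and GZMA passed with each array left out, and 31 were lost without SKMM1 day 4. For both granzymes the KMS12 ratios, which lay near 0, enter these tests and lower the pooled spread. Replication-dependent histones rose in SKMM1, 11 of 22 members against 0 lower (17 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 2.86e-17, adjusted p = 0.0831 with an estimated correlation), with H3C10 at 1.12 and H2BC12 at 0.89. Ribosomal proteins rose, 3 of 51 against 0 lower (27 and 0 adjusted over the list alone, median 0.40, adjusted p = 1.38e-14, adjusted p = 0.0831 with an estimated correlation), with RPS28 at 0.70. T and NK markers rose, 5 of 21 against 0 lower (8 and 0 adjusted over the list alone, median 0.28, adjusted p = 1.63e-10, adjusted p = 0.0305 with an estimated correlation), including NKG7 at 0.61 beside both granzymes. Interferon-stimulated genes rose, 6 of 41 against 0 lower (13 and 0 adjusted over the list alone, median 0.23, adjusted p = 3.45e-09, adjusted p = 0.0305 with an estimated correlation), with MX1 at 0.94 and OASL at 0.64. The p53 targets rose, 2 of 28 against 0 lower (5 and 0 adjusted over the list alone, median 0.09, adjusted p = 0.0105, adjusted p = 0.0831 with an estimated correlation), with PHLDA3 at 0.85, and lost their call without SKMM1 day 4 (0.0532). Without SKMM1 day 4 the single calls of H3C10 (adjusted p = 0.21), H2BC12 (0.111), RPS28 (0.34), NKG7 (0.232), MX1 (0.182), OASL (0.0764) and PHLDA3 (0.0819) were lost too. Those of RPS28, NKG7 and MX1 were lost also without SKMM1 day 2 (0.145, 0.179 and 0.13) or KMS12 day 2 replicate 1 (0.076, 0.0689 and 0.061). RPS28 was lost further without KMS12 day 4 replicate 2 (0.0551) or 3 (0.0507), and NKG7 without KMS12 day 4 replicate 1 (0.0584).

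Glycolysis was lower in SKMM1, with 22 of 23 members negative and ENO2, an enolase, past the test over all genes at -1.01 (11 lower and 1 higher adjusted over the list alone, median -0.43, camera adjusted p = 1.22e-10, adjusted p = 0.126 with an estimated correlation). Cholesterol and fatty acid synthesis was lower, with 4 of 33 past the test and 0 higher (14 and 0 adjusted over the list alone, median -0.22, adjusted p = 6.97e-10, adjusted p = 0.0652 with an estimated correlation), with SQLE at -0.50. Plasma cell identity was lower, with 24 of 27 members negative (median -0.24, adjusted p = 3.46e-05, adjusted p = 0.0305 with an estimated correlation). In that list CXCR4, a chemokine receptor, rose by 1.07 and BHLHA15, a secretory cell transcription factor, fell by 0.68, and 5 fell and 1 rose adjusted over the list alone. Without SKMM1 day 4 the calls of ENO2 (adjusted p = 0.14), SQLE (0.199), CXCR4 (0.17) and BHLHA15 (0.342) were lost. Without SKMM1 day 2 those of SQLE (0.105), CXCR4 (0.0922) and BHLHA15 (0.124) were lost. BHLHA15 was lost also without KMS12 day 2 replicate 1 (0.0876), day 2 replicate 2 (0.0518), day 4 replicate 2 (0.0671) or day 4 replicate 3 (0.0717). All 3 list calls ended with median centring, with medians of -0.14, -0.04 and -0.20 relative to all genes.

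DNA replication (median -0.10, adjusted p = 0.00424, adjusted p = 0.0831 with an estimated correlation) and G2 and mitosis (median -0.09, adjusted p = 0.00672, adjusted p = 0.366 with an estimated correlation) were lower in SKMM1 with 0 of 40 and 0 of 35 members past limma's test, over all genes and adjusted over the list alone. The ATF4 targets (1 of 37 lower, 3 adjusted over the list alone, median -0.14, adjusted p = 0.00672, adjusted p = 0.645 with an estimated correlation), the unfolded protein response (1 of 35, 2 adjusted over the list alone, median -0.07, adjusted p = 0.0104, adjusted p = 0.474 with an estimated correlation) and immediate early genes (1 of 26, 3 adjusted over the list alone, median -0.12, adjusted p = 0.0104, adjusted p = 0.146 with an estimated correlation) were lower too. The ATF4 member that fell was the secreted stanniocalcin STC2 (-1.10; adjusted p = 0.197 without SKMM1 day 4). The ATF4 list turned to 0.14 without SKMM1 day 2 (adjusted p = 0.306). The unfolded protein response and immediate early genes lost their calls without it (0.269 and 0.0656). DNA replication lost its call without SKMM1 day 4 (0.0532). The strict filter ended the ATF4 and immediate early calls, and the value table that of G2 and mitosis. Median centring in place of loess ended the immediate early call and turned the other 4, to 0.16, 0.16, 0.04 and 0.16 relative to all genes in the order given. Of these DNA replication (adjusted p = 0.00143), G2 and mitosis (0.00247) and the unfolded protein response (0.00754) passed as higher.

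The other 7 lists did not pass in SKMM1, with medians of 0.04 for mature B cell identity (adjusted p = 0.989), -0.04 for MYC targets (0.288), 0.07 for apoptosis regulators (0.902), -0.10 for NF-kB targets (0.0845), 0.07 for oxidative phosphorylation (0.569), 0.01 for monocyte and macrophage markers (0.804) and -0.07 for stromal and epithelial markers (0.836). Over all genes 1 member of mature B cell identity, 1 of NF-kB targets and 1 of stromal markers rose, and 1 MYC target and 3 NF-kB targets fell. Adjusted over the list alone, 1 rose in mature B cell identity, 1 fell in MYC targets, 1 rose and 3 fell in apoptosis regulators, 1 rose and 4 fell in NF-kB targets, 2 rose in stromal markers and 0 passed in the other lists. For monocyte and macrophage markers the mean and camera's direction were negative against that median. With median centring MYC targets turned to 0.21 and mature B cell identity to -0.37 relative to all genes, both past the test. Monocyte markers turned to -0.20, and oxidative phosphorylation was called (0.41). All SKMM1 arrays shared slide 3, so slide as a block within KMS12 could not change the SKMM1 medians. It ended no call.

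Among the changes shared by both lines, PARP12, an interferon-induced ADP-ribosyltransferase, rose by 1.34 in KMS12 (SE 0.13, n = 6) and 1.20 in SKMM1 (SE 0.18, n = 3). The lymphocyte surface antigen CD52 rose by 0.98 and 1.42, IFI6 by 0.97 and 0.98, the chemokine receptor CCR1 by 1.00 and 0.95, CD2 by 0.88 and 1.29, CXCR4 by 0.86 and 1.07, TP53INP1 by 1.08 and 0.84 and the Wnt inhibitor APCDD1 by 0.68 and 0.86, with APCDD1 well above background in untreated KMS12 cells on 1 of 8 arrays. PROCR was so in induced SKMM1 cells on 2 of 4. KLF2 fell by 1.63 and 2.45, the growth factor BMP6 by 1.13 and 0.97, PROCR by 0.95 and 1.47, glycine decarboxylase GLDC by 0.94 and 1.26, steroid sulfatase STS by 1.09 and 0.84, ARG2 by 0.81 and 1.59 and POFUT4 by 0.74 and 1.09.

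In all 138 genes passed in both lines in the same direction, 75 higher and 63 lower, against 18 and 16.1 expected of independent lists of these sizes, and 15 passed in opposite directions. Both lines had untreated RNA of their own, yet a probe's dye bias is common to both and adds to this overlap. Across 23892 genes, which are not independent replicates, the averages of the lines correlated at r = 0.426 (rho 0.477). For day 6 minus day 2, where dye bias cancels, r was 0.265 (rho 0.249), and 322 of 427 genes (75.4%) that differed at least 2-fold in KMS12 had the same sign in SKMM1. With every array kept the shared count ran from 44 with the value table to 716 with all 12 arrays as separate samples, and was 282 with the handling listed beforehand, 269 with slide as a block, 3 without SKMM1 day 4, 48 without SKMM1 day 2, 38 without KMS12 day 2 replicate 1 and 49 without KMS12 day 4 replicate 2. In SKMM1, of the named genes, only PROCR of 15 passed without the day 4 array, 7 of 15 passed without SKMM1 day 2 and 8 of 15 without KMS12 day 2 replicate 1. STS was lost in SKMM1 also without KMS12 day 2 replicate 2 or day 4 replicate 1, 2 or 3, TP53INP1 without day 4 replicate 2 or 3 and POFUT4 without day 4 replicate 2. In KMS12 14 of 15 passed with each array left out, and ARG2 was lost without KMS12 day 2 replicate 1, day 4 replicate 2 or day 6 replicate 1.

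The line difference, a direct test of KMS12 minus SKMM1 in which dye bias cancels, called 180 genes, 99 higher in KMS12 and 81 lower. Of these, 62 were not well above background in a channel on any array of a line, 51 of them in both channels, so that they have only a bound there or none. GZMA, CCR7, FAM43A and STC2 are among the 62 and are given no difference. GZMB rose in SKMM1 and did not pass in KMS12, with a difference of -2.53 (SE 0.09, adjusted p = 0.000105). FXYD2 and VAV3 differed by -1.84 and -1.52. In untreated KMS12 cells FXYD2 was well above background on 2 of 8 arrays, VAV3 on 1 and GZMB on 6, and in induced cells FXYD2 and VAV3 on 7, so these differences are imprecise. CCR7 was not well above background in untreated KMS12 cells and rose there at least 1.31-fold. PLAAT2, well above background in untreated SKMM1 cells on 3 of 4 arrays, differed by -2.28 through its fall in KMS12. ADM, WNT10A, a Wnt ligand, the cytokine IL16 and HOMER3 were higher in KMS12 relative to SKMM1, by 2.88, 2.32, 2.01 and 1.86. All SKMM1 arrays lay on a slide of their own, so slide and line cannot be told apart here. With every array kept the count ran from 23 with the strict filter on dim probes to 1094 with all 12 arrays as separate samples, and was 426 with the handling listed beforehand, 288 with slide as a block, 7 without SKMM1 day 4, 13 without KMS12 day 2 replicate 1, 35 without KMS12 day 4 replicate 2, 92 without KMS12 day 6 replicate 1 and 23 without the near-identical pair. GZMB and FXYD2 passed with each array left out. VAV3 was lost without SKMM1 day 4. The other 5 were lost without SKMM1 day 4 or KMS12 day 2 replicate 1, and 4 of these (all but IL16) also without KMS12 day 4 replicate 2. Further losses were ADM without KMS12 day 6 replicate 1, ADM and WNT10A without KMS12 day 2 replicate 2, and ADM without KMS12 day 4 replicate 1 or 3.

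Time of induction gave no single gene past the test. Day 6 minus day 2 called 0 genes with limma, against 1918 at an unadjusted p under 0.05, and 1 with the handling listed beforehand. None of the 20 lists passed with an estimated correlation, and the following camera calls hold only at the preset correlation. With fry, MYC targets and cholesterol synthesis passed as well (adjusted p = 0.0228 each) and ATF4 targets did not (adjusted p = 0.249). The ratios of MYC targets and ribosome biogenesis were higher at day 6 relative to day 2 (37 of 44 members positive, median 0.28, camera adjusted p = 5.09e-10, adjusted p = 0.0811 with an estimated correlation). ATF4 targets (34 of 37 negative, median -0.61, adjusted p = 3.52e-09, 0.36 with an estimated correlation) and cholesterol synthesis (28 of 33 negative, median -0.35, adjusted p = 3.52e-09, 0.0811 with an estimated correlation) were lower. Adjusted over the list alone, 4 MYC targets were higher and 5 ATF4 targets and 10 cholesterol genes lower, with 0 over all genes. Within slides 1, 2 and 3 the medians were 0.13, 0.43 and 0.44 for MYC targets, -1.20, -0.58 and 0.11 for ATF4 targets, and -0.32, -0.48 and -0.23 for cholesterol synthesis. With slide as a block these medians stayed at 0.28, -0.61 and -0.35. Days 2 and 6 were balanced over slides 1 and 2, so the block could not change them. For MYC targets the untreated channel moved from day 2 to day 6 by a median of -0.29, -0.38 and -0.33 on slides 1, 2 and 3. The induced channel moved by -0.19, 0.065 and 0.12. The higher ratio thus lay mainly in a lower untreated channel, though on slide 1 both channels fell. These moves compare a single channel across arrays, so they cannot tell a change of the untreated cells from a difference between arrays. In KMS12 the untreated channel held more of the spread between days than the induced channel. Among the brightest 3847 genes the ratio of spreads was 2.37 on slide 1 and 2.51 on slide 2, and 1.1 in SKMM1 on slide 3. Over all 15387 genes well above background in both channels on every array, the spreads were 0.556 against 0.258, 0.441 against 0.19 and 0.283 against 0.279.

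**Figure D3:**
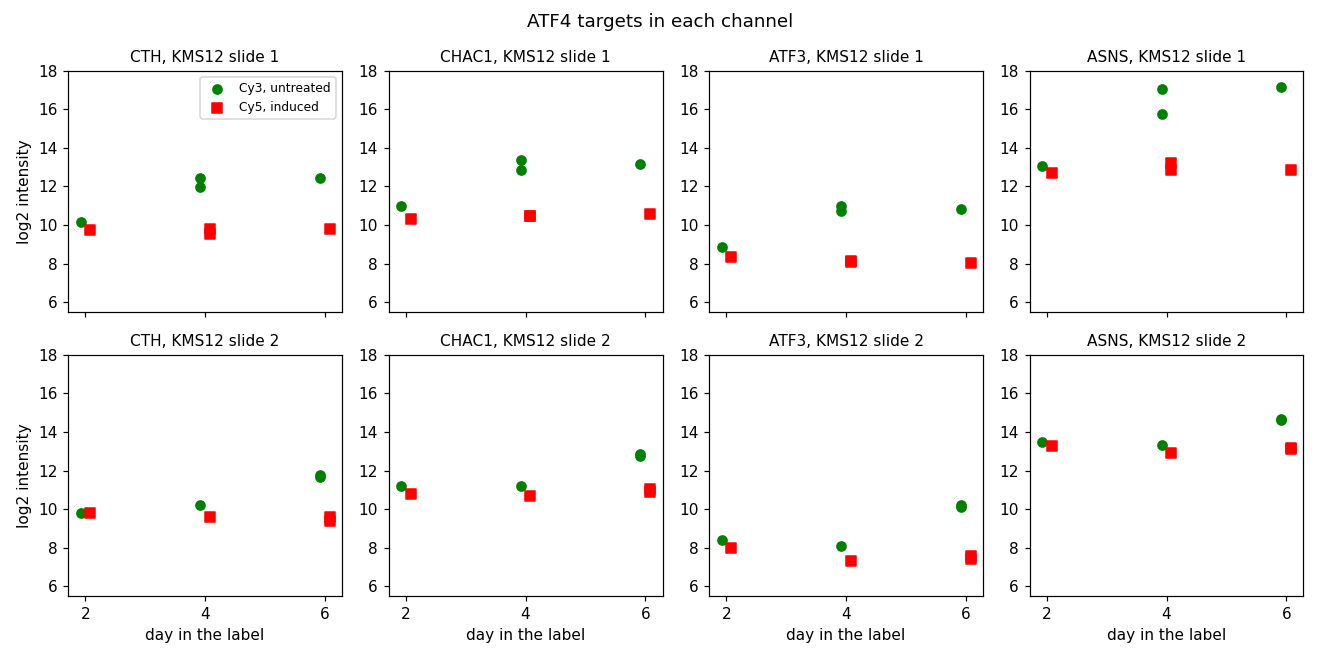
Log2 intensity of the ATF4 targets CTH, CHAC1, ATF3 and ASNS in the untreated (Cy3) and induced (Cy5) channels of the KMS12 arrays by labelled day, quantile normalized over all channels, with a point per array and slides 1 and 2 in rows. For CTH on slide 1, Cy3 goes from 10.1 at day 2 to 12.4 at day 6 and Cy5 from 9.72 to 9.81.

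Single days of KMS12 against untreated cells called 0 genes at day 2, 0 at day 4 and 0 at day 6 with limma in the fit of group means, against 2852, 3660 and 3078 at an unadjusted p under 0.05. With the handling listed beforehand they called 8, 57 and 548. IRF4 stood at -0.87 (SD 0.43, n = 2) at day 2, -0.82 (SD 0.35, n = 2) at day 4 and -0.58 (SD 0.67, n = 2) at day 6, and MYC at -0.43, -0.78 and -0.65. Without day 4 replicate 3, 7 genes were called at day 4. In SKMM1, with 1 sample a day, IRF4 was -0.85, -0.14 and -0.40 and MYC -0.74, -0.68 and -0.55.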

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

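The tests of explanations were chosen after the results were seen, except those of a shared change of the untreated cultures and of other splits of the samples, whose bounds were set before their values were seen, though the rule for the label of the former was changed afterwards. The lines differed by direct test in 180 genes, of which 62 have only a bound or none in a line because of dim signal there. In the 81 splits of the 9 samples into 6 and 3 that the fit with day allows, 1 gave as many, the real one, and the highest of the others gave 0. Every other split mixes the lines, so that the line difference enters its spread, and the samples are not independent. The splits therefore cannot exclude chance. Variation between time courses stays open too, since the SKMM1 samples were days of 1 course, as does slide, since they shared a slide. Without the near-identical KMS12 arrays the count was 23, and the splits were not repeated there.

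Of the largest line differences, those given here were ADM 2.88, WNT10A 2.32, IL16 2.01, HOMER3 1.86, GZMB -2.53, PLAAT2 -2.28, FXYD2 -1.84 and VAV3 -1.52. Among list members the germinal centre repressor BCL6 differed by -0.74, with 3 of 8 KMS12 arrays well above background in Cy3 and 2 in Cy5, and the lactate exporter SLC16A3 by 1.04. PHLDA3 differed by -0.99, IFITM1 by 0.80, OASL by -0.60 and TNF by 1.00, which turned to -0.053 with the strict filter on dim probes. In KMS12 PHLDA3 was well above background on 5 of 8 arrays in Cy3 and 4 in Cy5 and OASL on 3 in Cy3, and in SKMM1 TNF was on 1 of 4 in Cy3 and 2 in Cy5. Without SKMM1 day 4 none of these 6 passed (adjusted p between 0.113 and 0.242), and none passed without KMS12 day 2 replicate 1 (between 0.0567 and 0.0874). Without KMS12 day 4 replicate 2 only PHLDA3 of them passed, and without KMS12 day 6 replicate 1 only PHLDA3 and IFITM1. OASL was lost without KMS12 day 4 replicate 1, SLC16A3 and OASL without KMS12 day 2 replicate 2, and BCL6, OASL and TNF without SKMM1 day 2.

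Of the lists, 9 passed camera at its preset correlation and 0 with an estimated correlation (adjusted p of the 9 between 0.344 and 0.664). At the preset correlation ATF4 targets were lower in KMS12 than in SKMM1 by a median of -0.59 (adjusted p = 1.83e-10), histones by -0.35 (9.54e-09), cholesterol synthesis by -0.12 (0.00588), T and NK markers by -0.11 (0.00127), MYC targets by -0.10 (0.025), ribosomal proteins by -0.10 (0.0149) and p53 targets by -0.15 (0.0443). Glycolysis was higher by 0.25 (0.00127) and NF-kB targets by 0.20 (0.0443). Over all genes 1 ATF4 target (STC2, not well above background in KMS12) was higher and 0 lower, with 3 and 18 adjusted over the list alone. Over all genes 2 T and NK markers (GZMB, and GZMA, not well above background in KMS12) and 1 p53 target were lower, 1 gene each of glycolysis and NF-kB targets was higher, and 0 passed in the other 4 lists. Adjusted over the list alone, T and NK markers had 6 lower and 1 higher, p53 targets 2 and 1, NF-kB targets 2 and 4, glycolysis 0 and 2, cholesterol synthesis 2 and 0 and histones 1 and 0. Relative to the median of all genes under median centring, cholesterol synthesis turned to 0.02 and MYC targets to 0.01, and these, histones, ribosomal proteins and p53 targets lost their calls. The value table and the Feature Extraction ratio ended those of T and NK markers, MYC targets, ribosomal proteins, p53 targets and NF-kB targets. With slide as a block their medians were -0.57, -0.34, -0.11, -0.08, -0.09, -0.10, -0.11, 0.28 and 0.20, and p53 targets lost their call (0.0671). Without SKMM1 day 4, cholesterol synthesis (0.196), p53 targets (0.219), NF-kB targets (0.0656) and ribosomal proteins (0.699) lost theirs. Without KMS12 day 2 replicate 2 so did MYC targets (0.0607), NF-kB targets (0.136) and ribosomal proteins (0.0762). MYC targets lost theirs also without KMS12 day 6 replicate 1 (0.0932), KMS12 day 4 replicate 3 (0.199) or SKMM1 day 2 (0.0741). The p53 targets lost theirs without KMS12 day 2 replicate 1 (0.0714) or day 4 replicate 1 (0.059), and NF-kB targets without KMS12 day 4 replicate 3 (0.199), SKMM1 day 2 (0.167) or SKMM1 day 6 replicate 1 (0.0501).

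Between day 6 and day 2, 9 lists passed camera at its preset correlation and 0 with an estimated correlation, whose adjusted p stands second here. They were MYC targets at 0.28, ATF4 targets at -0.61, cholesterol synthesis at -0.35, NF-kB targets at -0.31 (adjusted p = 0.000398 and 0.0811), glycolysis at -0.24 (0.001 and 0.52), ribosomal proteins at -0.23 (4.15e-06 and 0.348), immediate early genes at -0.19 (3.35e-05 and 0.0811), mature B cell identity at -0.16 (0.0482 and 0.334) and interferon-stimulated genes at -0.15 (0.00935 and 0.274). Adjusted over the list alone 2 NF-kB targets and 2 immediate early genes were lower. Within slides 1, 2 and 3 the last 6 stood at -0.13, -0.14 and -0.21 for NF-kB targets, -0.34, 0.14 and -0.55 for glycolysis, -0.36, -0.05 and -0.19 for ribosomal proteins, -0.25, -0.41 and -0.26 for immediate early genes, -0.15, -0.14 and -0.05 for mature B cell identity and -0.12, -0.26 and -0.06 for interferon-stimulated genes. Mature B cell identity lost its call with slide as a block (0.0524) and without KMS12 day 4 replicate 1 (0.0704), day 6 replicate 1 (0.241), day 2 replicate 2 (0.145) or day 6 replicate 3 (0.0544), or SKMM1 day 2 (0.148), day 4 (0.0615) or day 6 replicate 2 (0.0571). Glycolysis lost it without SKMM1 day 2 (0.2) and interferon-stimulated genes without KMS12 day 2 replicate 1 (0.0504). The 10 splits of the 6 samples of days 2 and 6 are too few for a share under 0.05, with 0 genes for the real split, 0 as the highest of the others, and 10 splits with as many.

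The KMS12 arrays labelled day 4 replicate 2 and day 6 replicate 1 were nearly identical in log ratio (r = 0.984). Other pairs on slide 1 correlated at 0.623 at most, which argues against likeness of arrays on a slide, and pairs of a day 4 and a day 6 array on the other slides differed by a MAD of at least 0.248 (0.058 for this pair), which argues against a response that is level in every course. In each channel alone the pair differed by at most 0.347 times the larger MAD of the closest pairs within a group, with a MAD of 0.104 in Cy3 against 0.121 and 0.299 for those pairs. A candidate explanation is that both arrays carried the same RNA, so that a day label is wrong, which these data cannot settle, and a course whose response stayed level from day 4 to day 6 stays open.

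In KMS12 the spread between days 6 and 2 lay mainly in the untreated channel. Dim Cy3 signal is argued against by the brightest 3847 genes, where that spread was at least 2.37 times the spread in Cy5, and exchanged channel labels by IRF4, lower in Cy5 on 12 arrays. A Cy3 difference between whole arrays was not tested and stays open. Median Cy3 intensity was 265.6 at day 2 and 178.1 at day 6 on slide 1. On slide 2 it was 106.9 at day 2 and 159.7 and 158.2 at day 6, and on slide 3 239.4 at day 2 and 280.1 and 241.8 at day 6. The move in Cy3 did not correlate between slides 1 and 2 over 15387 genes (r = 0.039), which met the bound set beforehand against a change common to the untreated cultures, in place of an earlier test on the ATF4 list that had raised and favoured it (1.28 in Cy3 against 0.07 in Cy5, and 0.57 against 0.01). After that value was seen the bound was judged wrong and its label changed to open, because it took in genes at large, while 18 of 20 lists moved the same way in Cy3 on both slides and 12 in Cy5, in Cy3 with MYC targets at -0.29 and -0.38, histones at 0.51 and 0.48 and cholesterol synthesis at 0.25 and 0.57, and the day 6 array of slide 1 is 1 of the 2 whose labels are in doubt. A change of the untreated cultures, common or particular to each, may therefore remain as a hypothesis, and the labels used here do not say whether untreated cells were collected on each day.

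IRF4 was lowered less on the KMS12 arrays of slide 2 (-0.27) than of slide 1 (-1.04). Compressed ratios on slide 2 are argued against by the spike-in controls, whose lowest slope there, 0.871, lay above the highest of slide 1, and a fault of the chosen probe by the other IRF4 probe, which differed by 0.987 in the same direction. The 3731 genes called in KMS12 moved on slide 2 by 0.676 times their median change on slide 1 (0.31 against 0.46). This is consistent with a weaker induction in the cells on slide 2, though those genes were called on both slides together, and a difference between the courses stays open because the labels used here do not tie arrays to courses throughout.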

How the results depend on the processing

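Alternatives that counted day 6 replicates 2 and 3 or the day 4 replicates 1 and 3 of KMS12 as 2 samples, or left out a near-identical array, were chosen after seeing the data. Of 5061 comparisons of named genes with an alternative 4326 kept direction and call, 719 kept the direction and lost the call and 16 changed sign, 14 of these under median centring, where 10 of the 14 keep their sign relative to the median of all genes. Of 2520 for lists 2330 stayed called in the same direction or stayed uncalled. Of the rest 147 lost the call, 25 gained it and 18 changed direction, 17 of these under median centring. A turned direction was counted only where the list was called in at least 1 of both settings. The cause of a change was not tested unless stated. The share of spots well above background, from 56.3% in Cy3, limits what dim genes can show.

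Median centring in place of loess, which leaves dye bias that depends on intensity, moved the median of all genes to 0.30 in KMS12, 0.17 in SKMM1 and 0.10 in the line difference. It called 2772, 637 and 268 genes at days 2, 4 and 6, 16655 in the KMS12 average (69.9% higher, against 53%), 569 line differences (44.8% higher, against 55%), 455 shared genes and 5 lists in the line difference, with 93.4% of SKMM1 calls higher, against 49.9%. IRF4 in KMS12 was -0.14 (adjusted p = 0.462, against 0.00203 to 0.0806 under the other alternatives). The sign changed in KMS12 for MYC (0.23), PA2G4 (0.14), RRS1 (0.14), CDC25C (0.26), CDC45 (0.21), CCND1 (0.23), MCM4 (0.16), PDIA6 (0.22) and CREB3L2 (0.11) and in SKMM1 for FDFT1 (0.083). Relative to the median of all genes these stayed lower but came nearer to it, MYC at -0.08 against -0.63, so the common shift is only part of the change. KIF2C (0.43), AURKA (0.33), KIF20A (0.32) and TCF7 (-0.064; not well above background in untreated KMS12 cells) changed sign relative to it too, to 0.13, 0.02, 0.02 and -0.37. Camera ranks a list against the other genes, and its direction can turn where the list's median keeps its sign. Lists called in at least 1 of both settings whose direction turned in KMS12, with their medians, were plasma cell identity (0.44), MYC targets (0.46), mitosis (0.61), DNA replication (0.52), cholesterol synthesis (0.26, or -0.04 relative to all genes), glycolysis (0.53), the unfolded protein response (0.55), apoptosis regulators (0.66, against 0.06) and T and NK markers (0.063, against 0.11). In SKMM1 they were mature B cell identity (-0.20), MYC targets (0.38), mitosis (0.33), DNA replication (0.33), the unfolded protein response (0.33) and ATF4 targets (0.21), and in the line difference MYC targets (0.11) and cholesterol synthesis (0.13). Other counted changes of sign were TNF in KMS12 (-0.22) and in the line difference (-0.053) under the strict filter, and ATF4 targets in SKMM1 without SKMM1 day 2 (0.14).

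The Feature Extraction ratio gave 189 genes in SKMM1 (63.5% higher), 71 line differences (40.8% higher), 61 shared and 4 lists in the line difference. The value table gave 98 in SKMM1 (63.3% higher), 44 shared, 110 of 172 named calls and 4 lists, with 38.3% of line differences higher. Scale normalization gave 2 genes at day 4, 2 at day 6, 969 in SKMM1, 356 line differences and 354 shared. The strict filter gave 102 in SKMM1, 23 line differences, 58 shared and 102 named calls. All 12 arrays as separate samples gave 190, 2130 and 1469 at days 2, 4 and 6, 6308 in KMS12, 1808 in SKMM1, 1094 line differences and 716 shared, and counts technical repeats as samples. KMS12 fitted alone gave 988 genes, with IRF4 still at -0.76 and not past the test (adjusted p = 0.0656), and has fewer samples. It gives no value for the line difference, day 6 minus day 2 or the number of named calls. Slide as a block gave 675 in SKMM1, 288 line differences and 269 shared.

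The handling listed beforehand gave 8, 57 and 548 at days 2, 4 and 6, 752 in SKMM1, 426 line differences, 1 between days and 282 shared. Day 4 replicates 1 and 3 as 2 samples gave 112 at day 4. With replicate 2 left out as well there were 88 shared, and with day 6 replicate 1 left out 90 at day 4, 1 at day 6 and 2021 in KMS12. Without both near-identical arrays there were 970 in KMS12, 23 line differences, 81 shared, 111 named calls and IRF4 at -0.51, not past the test. With an estimated correlation camera called 0 lists in KMS12, 3 in SKMM1, 0 in the line difference and 0 between days, and fry 2 in the line difference and 4 between days.

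With each array left out in turn, counts ran from 1079 to 3763 in KMS12, 13 to 437 in SKMM1, 7 to 190 for the line difference, 3 to 141 shared, 0 to 7 at day 4, 98 to 172 named calls and 5 to 9 lists in the line difference, and IRF4 in KMS12 from -0.86 to -0.64.

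The replicate numbers within KMS12 were not used as pairs in the reported fits. Deviations of the 7 same-numbered pairs correlated between -0.809 and 0.590, against -0.813 to 0.843 for 14 other pairs. Deviations of the 2 day 2 arrays mirror each other, which forces values of both signs, so this cannot exclude a pairing. By slide, 10 pairs on the same slide ran from -0.357 to 0.843 and 11 on different slides from -0.813 to 0.346. With the number as a replicate block on 12 arrays there were 6, 2143 and 1059 genes at days 2, 4 and 6, 5174 in KMS12, 1418 in SKMM1, 766 line differences, 0 between days and 528 shared, and 5 list calls changed.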
